A study of Mus musculus with 4 samples.

How the data were processed

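Single-cell RNA was measured in islets of Langerhans from female C57BL/6J mice that had all received diphtheria toxin, 4 injections 48 hours apart from postnatal day 2. The animals either carried the CCR2-DTR transgene, which places the toxin's receptor on CCR2-expressing cells, or were WT littermates, and were taken at 1 or 6 months of age. Per the labels, each library held 300 islets pooled from 2 to 3 females, freshly isolated with collagenase, a Ficoll gradient and hand picking, and was made on the 10x Chromium platform. There was 1 library for each of the 4 combinations of genotype and age.

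The deposited matrices hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 5.0.1 on the mm10 build. The other deposited files are of a different kind (unit: other), since they name the barcodes and the genes and hold no measurement. The values were checked to be whole numbers with totals that differ between barcodes, over 32285 genes in each library, and every barcode listed held at least 500 UMIs. The annotation release and whether introns were counted are not given in the sources used here. The barcodes had already been called as cells by the authors, and empty droplets are not in the files, so free RNA could not be measured directly or subtracted. Gene coordinates come from GENCODE vM21 on GRCm38.

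Barcodes with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs were kept. Doublets were removed where the Scrublet score (scanpy 1.11.5) passed 0.25 in any library. This common threshold was set after the data were seen, because the automatic threshold marked 0 of the filtered barcodes in the CCR2-DTR 1-month library and 1 in the CCR2-DTR 6-month library. All 4 libraries were clustered together: counts were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen with the library as batch, and 30 principal components and a graph of 15 neighbours were used. No batch correction was applied, since genotype and age coincide with the library. Digestive enzyme and haemoglobin genes were kept out of the variable genes, a choice made after the data were seen, because they otherwise divided cells by free RNA. Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) gave 24 clusters.

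Clusters were named from 25 marker sets fixed, like the filters, the comparisons, the gene lists, the rule for named genes and most alternatives, before the data were examined. A cluster took the class with the highest mean marker level. It stayed unnamed when under 3 markers stood out, when its 10 leading genes held as many markers of another class, or when its UMI count was low and none of its leading genes was a marker. Classes are called beta-like, alpha-like and so on, since they rest on RNA alone. Cells of the cycling cluster were given the class whose marker profile they resembled most.

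Each group is 1 library of pooled animals, so no test between groups was run and cells were not treated as replicates. Shares of cells have exact Clopper-Pearson 95% intervals. For genes, the counts of all cells of a class were summed per library and divided by the class total to give CPM, and 2 libraries were compared by the ratio of CPM with an exact conditional 95% interval for 2 Poisson counts. These intervals cover counting error only, not the spread between cells, animals or dissociations. A count of 0 was set to the 3 counts it allows, and the ratio is then given as a bound. Where an alternative left a gene with 0 counts in both libraries it gave no value, and a bound that points against the counts was not taken as a change of sign, rules added after the data were seen. A class was compared where both libraries held at least 50 cells. Each of the 6 classes so compared had 4 comparisons, namely genotype at 1 month, genotype at 6 months, and age within each genotype.

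Gene lists were summarised over members with at least 50 CPM in at least 1 of the 2 libraries and at least 10 UMIs over both. Given are the number of members above and below the median gene, the median log2 ratio less that of all genes past the same floor (the relative median), and its percentile among 10000 random lists of the same size matched on expression in 20 bins. The interval of a relative median comes from 500 Poisson redraws of the counts. The 28 lists hold 681 entries, of which 680 were found in the files: beta identity and maturity, immature and disallowed genes, unfolded protein response, proliferation, senescence and ageing, oxidative phosphorylation, glycolysis and hypoxia, secretory granule and exocytosis, interferon response and antigen presentation, immediate early and dissociation response, inflammatory and NF-kB response, cholesterol synthesis, antioxidant, circadian clock, alpha identity, delta identity, islet hormones, monocyte-derived, resident macrophage, macrophage antigen presentation, macrophage inflammatory cytokines, lipid-associated macrophage, trophic factors, extracellular matrix, islet endothelium, ribosomal protein genes, mitochondrial genes and acinar genes. Several lists share members.

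Named genes are the 10 highest and 10 lowest ratios in the beta-like class for each genotype comparison and for age in WT, 5 and 5 for age in CCR2-DTR, 10 and 10 for genotype in the macrophage-like class, and 3 and 3 elsewhere. They had to reach 50 CPM, have an interval that leaves out equality, and lie at most 5-fold below their level in any other class. Markers of other classes and mitochondrial, ribosomal protein, haemoglobin and predicted genes were left out. The 10 beta-like genes furthest to the same side at both ages, in each direction, were also named. The low-UMI clusters and the Ghrl-led cluster were not among the other classes of this rule. Chemokine receptor genes, digestive enzymes and genes of T-like and B-like cells outside the rule were chosen after their values were seen.

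The share of proliferating cells counts cells with a UMI of at least 3 of the 25 proliferation genes after every cell had been thinned to 2000 UMIs, with shallower cells left out. Counts with known ratios were simulated as Poisson draws from the class means, with no spread between cells or animals. Of genes raised or lowered 1.25-fold, 100% had an interval on the right side in the beta-like 1-month comparison (1828 genes). The same held in the alpha-like 6-month comparison (2202 genes). In the macrophage-like 6-month comparison (2641 genes) these shares were 38.8% at 1.25-fold, 85.1% at 1.5-fold and 95.5% at 2-fold. In the endothelial-like 1-month comparison (3541 genes) 80.6% were found at 1.25-fold. The intervals, which assume such counts, held the true ratio for 95.9% of genes in the beta-like and 95.0% in the macrophage-like comparison. That coverage does not extend to genes whose RNA lies mostly in a single cell. A list shifted by 0.3 on the log2 scale was returned as 0.3 in the beta-like and as 0.25 in the macrophage-like comparison.

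The alternatives were a stricter and a looser cell filter, doublets kept, Leiden resolution 2, shares outside the acinar-like class, TMM scaling (edgeR 4.0.16, R 4.3.3), a class total without hormone, acinar and mitochondrial genes, the mean of each cell's own CPM, cells thinned to 2000 UMIs, beta-like cells without another hormone, floors of 20 and 200 CPM and no CPM floor, and 2 proliferation genes or no thinning. Added after the data were seen were Scrublet's automatic thresholds, enzyme and haemoglobin genes used in the clustering, shares outside the low-UMI clusters or with these counted under their best class, beta-like cells outside the cluster of highest doublet score or outside the cycling cluster, beta-like cells outside a cluster with folding genes among its leading genes, cells under 10% hormone UMIs, endothelial-like cells outside a small haemoglobin-led cluster, mesenchymal-like cells outside a collagen-led cluster, and alpha-like cells of the largest alpha-like cluster. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. Classes under 50 cells in a library were compared by share only. Results of some single genes are not reported here.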

Results

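The data are 4 single-cell RNA libraries of mouse pancreatic islets, 1 for each combination of genotype (WT or CCR2-DTR) and age (1 or 6 months). In CCR2-DTR mice a transgene gives cells that express the chemokine receptor CCR2, mainly monocytes and cells derived from them, the receptor for diphtheria toxin. All animals received the toxin in the first days of life, so the libraries describe islets long after the time of depletion. The files list 10433 barcodes for WT at 1 month, 12444 for CCR2-DTR at 1 month, 5089 for WT at 6 months and 7113 for CCR2-DTR at 6 months, with 121292320, 96744006, 60315217 and 81917159 UMIs. After filtering, 8705, 8625, 3638 and 4283 cells remained in the same order, at a median of 11101, 8868, 12835 and 14811 UMIs. In both CCR2-DTR libraries more barcodes passed 15% mitochondrial UMIs, a common sign of damaged cells: 18.4% against 9.37% at 1 month and 23.9% against 12.2% at 6 months. Genes called highest, lowest or furthest apart are so among those admitted by the rule for named genes, which leaves out markers of other classes, genes more than 5-fold below their level in another class, and mitochondrial, ribosomal protein, haemoglobin and predicted genes. Each group is 1 library, so intervals throughout cover counting error only, and no difference below has been tested between animals.

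The genotype label was visible in the RNA of every main cell class. Ccr2 and Ccr3, chemokine receptor genes normally read in immune cells, had UMIs in beta-like, alpha-like, delta-like, endothelial-like and mesenchymal-like cells of both CCR2-DTR libraries and almost none in WT. Summed over these 5 classes, Ccr3 had 364 UMIs in CCR2-DTR and 1 in WT at 1 month (469-fold per UMI, interval 83.6 to 18600), and 289 and 2 at 6 months (105-fold, 28.8 to 872). Ccr2 had 155 against 1 and 127 against 1 UMIs (200-fold, 35.3 to 7930, and 92.3-fold, 16.3 to 3680). Both genes lie close together on chromosome 9 (GRCm38), Ccr3 at 124021972 to 124031689 and Ccr2 at 124101950 to 124113557. Ccr1, upstream at 123962124 to 123968692, had 4 against 1 UMIs at 1 month and 1 against 0 at 6 months. The flanking genes Lztfl1 (log2 ratio 0.19 and 0.08) and Fyco1 (0.18 and -0.05) were near equality. Among 18405 genes scanned in these 5 classes, 21 were higher in CCR2-DTR at both ages with a lower bound above 2 on the log2 scale, Ccr3 and Ccr2 among them, and 12 of the 21 are on the acinar list. The share of beta-like cells with a Ccr2 UMI was 0.0264% and 2.38% at 1 month and 0% and 5.08% at 6 months, WT first, at median depths of 17364, 14074, 28930 and 27649 UMIs. In macrophage-like cells, where Ccr2 is expected, it was 16.8%, 41.1%, 42.6% and 41.5% in WT at 1 month, CCR2-DTR at 1 month, WT at 6 months and CCR2-DTR at 6 months, at median depths of 4573, 5259, 8185 and 7563 UMIs. Xist UMIs were in 96.3% to 98.3% of cells, and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together had 2, 1, 3 and 4 UMIs per library, matching the label female in all 4.

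**Figure D1:**
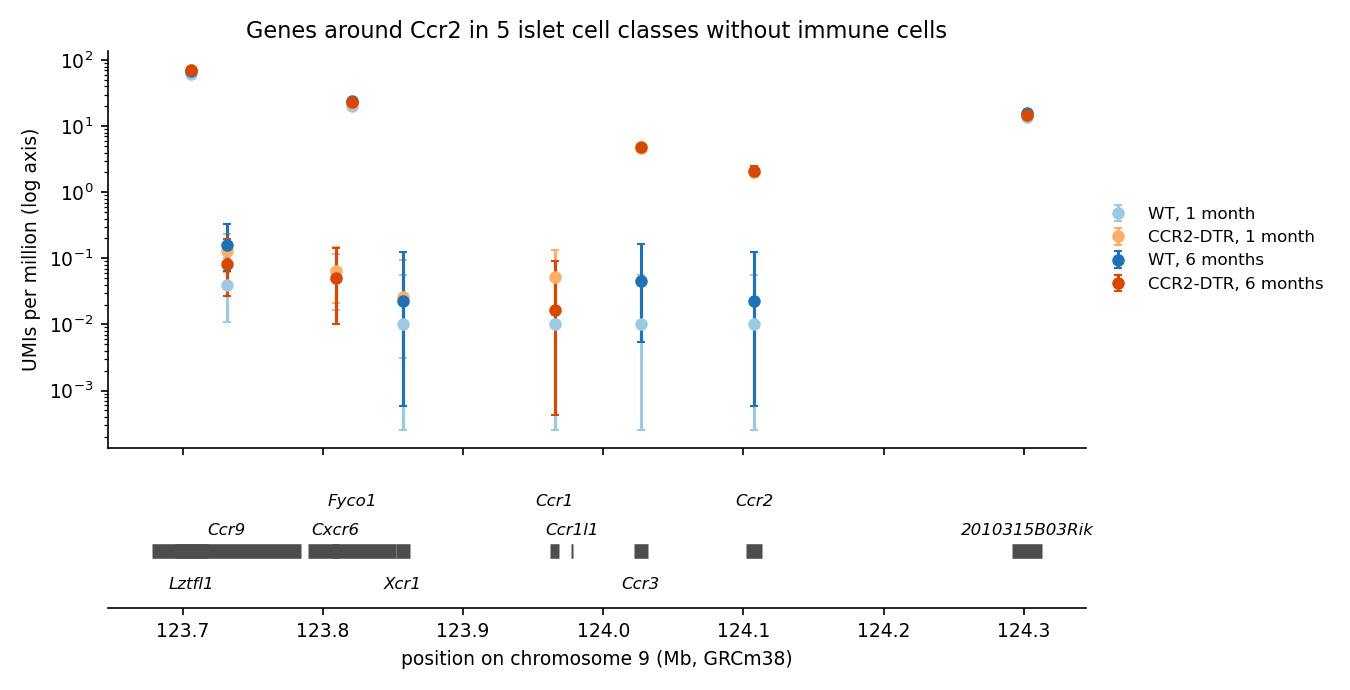
CPM of genes around Ccr2 on chromosome 9 (log axis, genes in order of position), summed over beta-like, alpha-like, delta-like, endothelial-like and mesenchymal-like cells of each library, with exact 95% Poisson intervals, counts of 0 not drawn. Ccr3 and Ccr2 stand far higher in both CCR2-DTR libraries than in WT, while Lztfl1, Fyco1 and 2010315B03Rik are alike.

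The series asks how depleting CCR2+ myeloid cells around birth affects the cell populations of the islet later on, which the shares of each class address. Beta-like cells made up a smaller part of the CCR2-DTR library at 1 month, while the direction at 6 months depended on whether 2 clusters of low UMI count are counted among them. Left unnamed, as their leading genes hold no marker, these clusters nevertheless score highest for beta cell markers. Without them beta-like cells were 43.5% of WT cells (interval 42.4 to 44.5) and 38.0% of CCR2-DTR cells (36.9 to 39.0) at 1 month, a ratio of 0.873 (0.833 to 0.915). At 6 months they were 21.0% (19.6 to 22.3) and 31.7% (30.3 to 33.2), a ratio of 1.51 (1.385 to 1.658). With them they were 43.9% and 41.4% at 1 month (ratio 0.943, 0.901 to 0.987) and 49.0% and 45.9% at 6 months (ratio 0.937, 0.878 to 0.999). T-like and B-like cells together were 0.385% of WT cells and 3.06% of CCR2-DTR cells at 6 months, 14 and 131 cells, a ratio of 7.95 (4.572 to 14.94). Macrophage-like cells, marked by C1qa, C1qb and Csf1r, were 1.57% and 1.75% at 1 month (ratio 1.11, 0.877 to 1.412) and 2.58% and 3.71% at 6 months (ratio 1.44, 1.106 to 1.874).

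Mesenchymal-like cells were 3.00% of WT and 4.72% of CCR2-DTR cells at 1 month (ratio 1.57, 1.344 to 1.846) and 1.59% and 2.48% at 6 months (ratio 1.55, 1.117 to 2.177). Alpha-like cells were 27.3% and 28.6% at 1 month and 19.1% and 20.9% at 6 months. Delta-like cells were 7.87% and 8.42%, then 9.21% and 7.73% (ratios 1.07, 0.962 to 1.189, and 0.839, 0.719 to 0.98). Endothelial-like cells were 7.43% and 7.85%, then 8.69% in both. A cluster led by Ppy and Pyy, hormones of the gamma cell, was 5.37% and 4.16% at 1 month and 7.06% and 4.72% at 6 months. At 1 month T-like and B-like cells were 0.230% and 0.417% (ratio 1.82, 1.024 to 3.312). The cluster named acinar-like has the acinar markers Try5, Prss2 and Zg16 among its leading genes, but also Tff3, Spp1 and Fcgbp, genes of other epithelia. It numbered 52, 53, 9 and 14 cells in WT and CCR2-DTR at 1 month and then at 6 months. In the same order Schwann-like cells numbered 27, 31, 14 and 12, and neuronal-like cells 6, 4, 4 and 3.

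Shares of other classes at 6 months also depend on these clusters, whose leading genes include noncoding RNAs such as Tsix and protein-coding genes such as Mlxipl. The clusters held 28.1% of WT cells and 14.2% of CCR2-DTR cells at 6 months but 0.402% and 3.41% at 1 month. Outside them beta-like cells were 29.1% (27.4 to 30.9) of WT and 37.0% (35.4 to 38.6) of CCR2-DTR cells at 6 months (ratio 1.27, 1.161 to 1.389). There the 6-month ratio of alpha-like cells was 0.916 (0.829 to 1.013), on the other side of 1 than over all cells (1.09, 0.989 to 1.209), with both intervals including 1. That of endothelial-like cells was 0.838 (0.719 to 0.977) in place of 1.0, that of delta-like cells 0.703 (0.602 to 0.821), and those of macrophage-like cells, 1.20 (0.927 to 1.571), and mesenchymal-like cells, 1.30 (0.936 to 1.824), had intervals that include 1. T-like and B-like cells stood at 6.66 (3.831 to 12.52). Among beta-like, alpha-like, delta-like and Ppy-led cells alone, beta-like cells were 37.2% and 48.7% at 6 months and 51.8% and 47.9% at 1 month. Against 1 month, the WT library at 6 months held fewer beta-like cells (ratio 0.482, 0.445 to 0.521, over all cells), fewer mesenchymal-like cells (0.532, 0.393 to 0.709) and more macrophage-like cells (1.64, 1.249 to 2.15). In CCR2-DTR the same ratios were 0.836 (0.784 to 0.891), 0.524 (0.419 to 0.651) and 2.12 (1.686 to 2.667), and T-like and B-like cells stood at 7.33 (5.034 to 10.913) times their 1-month share. Outside the low-UMI clusters the beta-like, mesenchymal-like and macrophage-like ratios with age were 0.667 (0.617 to 0.722), 0.736 (0.544 to 0.982) and 2.27 (1.73 to 2.978) in WT and 0.941 (0.883 to 1.003), 0.590 (0.472 to 0.733) and 2.39 (1.898 to 3.003) in CCR2-DTR. With these clusters counted as beta-like, the beta-like ratios turned to 1.12 (1.056 to 1.183) and 1.11 (1.05 to 1.173). At resolution 2, where part of the macrophage-like cluster becomes unnamed, the 1-month macrophage-like ratio, whose interval includes 1, went from 1.11 to 0.819.

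**Figure D2:**
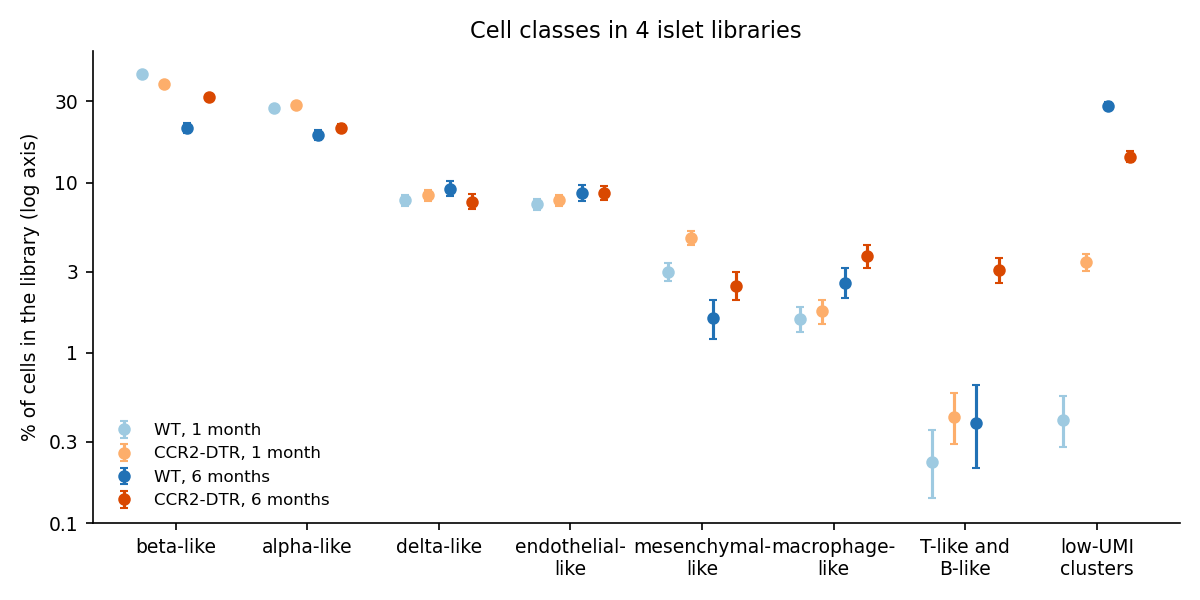
Percent of cells of each library in each class, with exact Clopper-Pearson 95% intervals, for WT and CCR2-DTR at 1 and 6 months. Beta-like cells lie lower in CCR2-DTR at 1 month (38.0% against 43.5%) and, with the low-UMI clusters apart, higher at 6 months (31.7% against 21.0%), and T-like and B-like cells reach 3.06% in CCR2-DTR at 6 months.

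In beta-like cells at 1 month (3274 CCR2-DTR and 3784 WT cells), CCR2-DTR had less insulin RNA and more RNA of endoplasmic reticulum chaperones. Ins1 was at 114400 CPM against 140100 and Ins2 at 285700 against 338500, and 47.3% of beta-like UMIs came from hormone genes against 53.5% in WT. Since insulin takes such a part of the total, the median gene stood 0.20 higher on the log2 scale in CCR2-DTR, and list values below are relative to it. For the unfolded protein response, the genes that help proteins fold in the endoplasmic reticulum, 14 of 18 measured members lay above the median gene and the relative median was 0.13 (0.11 to 0.14, percentile 100 among random lists). That value was 0.06 with no CPM floor and 0.18 outside the beta-like cluster that has Sdf2l1 and Fkbp11 among its leading genes. Sdf2l1 was at 433.2 against 304.7 CPM, Creld2 at 167.7 against 117.9 and Hspa5 at 928.4 against 712.6. Of the beta identity and maturity list, 22 of 26 members lay below the median gene (relative median -0.14, -0.15 to -0.12, percentile 0.02). Against the raw totals 19 of its 26 members were higher, among them the amylin gene Iapp at 63810 against 49850 CPM, while Mafa was at 239.6 against 267.9.

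Genes of the respiratory chain and of ribosomes were low at 1 month. Oxidative phosphorylation had 28 of 40 members below the median gene (relative median -0.19, -0.22 to -0.17, percentile 0), and ribosomal protein genes 59 of 80 (-0.24, -0.25 to -0.22, percentile 0). The 4 measured immature and disallowed genes, which mature beta cells keep low, were higher (0.39, 0.34 to 0.43), with Sox4 at 124.0 against 53.44 CPM and Cd81 at 91.91 against 57.12. Immediate early genes (0.17, 7 of 9 above the median gene) and cholesterol synthesis (0.14, 4 of 6) were also higher. Senescence and ageing (0.07, 4 measured, Bambi 62.4 against 33.55), antioxidant (0.04) and glycolysis (0.07) stood near the median gene, as did secretory granule genes (0.01) and mitochondrial genes (-0.01). Antioxidant and glycolysis turned sign under some settings. Delta identity (-0.19) and alpha identity (-0.08) lay below it, the latter with a sign that depended on the floor. Islet hormones (0.04) combined the lower insulins with Gcg, a transcript of alpha cells, at 0.431% against 0.271% of UMIs, and turned to -0.23 with doublets kept.

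Among genes that the naming rule admits, which at 1 month do not include Sox4 and Bambi, the one furthest higher in CCR2-DTR was Rgs2, a regulator of G protein signalling, at 269.4 against 51.69 CPM (5.21-fold, log2 2.38, 2.33 to 2.44). Usp51 (2.11-fold), Nnat (1.99-fold), a small protein implicated in insulin processing, Car15 (1.94-fold) and Mdm1 (1.92-fold) followed, then P2ry1, a purinergic receptor (1.80-fold), Fkbp5 (1.67-fold), the clock gene Cry2 (1.61-fold), Nudt4 (1.61-fold) and Tmtc3 (1.58-fold). Car15 leads the beta-like cluster of highest doublet score, which held 15.4% of WT and 21.3% of CCR2-DTR beta-like cells at 1 month. At 6 months that cluster held 23.6% and 16.7%. The lowest was the metallothionein Mt1 at 173.4 against 273.7 CPM (1.58-fold lower, log2 -0.66, -0.70 to -0.62). The other 9 lowest genes were between 1.31-fold and 1.44-fold lower and encode mostly small mitochondrial or secretory pathway proteins: Dpm3, Atp5e, Romo1, Tomm7, Anapc13, Uqcr11, Tmem256, Sec61g and Ndufa5. Digestive enzyme RNA differed in the same cells: 73.8% of CCR2-DTR and 12.7% of WT beta-like cells held an acinar UMI at 1 month, and 74.6% and 9.12% of endothelial-like cells, which do not make these enzymes, at median depths of 3920 and 3145 UMIs.

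At 6 months (1359 CCR2-DTR and 762 WT beta-like cells) the insulin genes were nearly level, Ins1 at 127100 against 128700 CPM and Ins2 at 330100 against 314200, and the gene furthest lower in CCR2-DTR was Cish. This gene, a feedback inhibitor of the JAK-STAT pathway, was at 11.44 against 58.91 CPM (5.15-fold lower, log2 -2.37, -2.53 to -2.21), and Cebpd at 28.8 against 73.78 (2.56-fold lower). Socs2 (1.42-fold lower) and the prolactin receptor gene Prlr, at 674.8 against 887.0 CPM, were among the 10 lowest too. The beta cell transcription factor gene Mafa was at 244.8 against 348.0 CPM (1.42-fold lower, log2 -0.51, -0.55 to -0.46). Folr1, Enpp2, Ivd, Lars2 and Gadd45g, between 1.43-fold and 1.92-fold lower, complete them. The 10 highest were Nnat at 59.9 against 27.35 CPM (2.19-fold, log2 1.13, 1.00 to 1.26), Gad1, the enzyme that makes GABA (1.73-fold), Sox4 (1.73-fold), Klhl24 (1.64-fold), P2ry1 (1.49-fold), Rgs2 (1.44-fold), the amino acid transporter genes Slc38a4 (1.42-fold) and Slc38a2 (1.34-fold), Mdm1 (1.41-fold) and Herpud1 (1.38-fold).

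By list at 6 months, where the median gene was level (-0.03), immediate early and stress genes stood highest: 9 of 10 measured members lay above the median gene (relative median 0.27, 0.22 to 0.30, percentile 100), with Egr1 at 117.8 against 94.7 CPM and Hsph1 at 86.5 against 70.27. Mitochondrially encoded genes were higher in 10 of 11 (0.18) and ribosomal protein genes slightly so (0.06, 68 of 80). Beta identity (0.03), oxidative phosphorylation (0.02), glycolysis (0.02), secretory granule (0.02), cholesterol synthesis (-0.01) and the unfolded protein response (-0.04) lay close to the median gene. The signs for beta identity and the unfolded protein response turned under some settings. Antioxidant (-0.04, 10 of 12 below), senescence and ageing (-0.11) and delta identity (-0.14) were low, and senescence and ageing turned to 0.08 in cells thinned to 2000 UMIs. The 4 immature and disallowed genes were lower by median (-0.31), with Cd81 at 46.54 against 73.87 CPM, except Sox4 at 101.6 against 58.6. The hormones of other islet cells were lower, Ppy at 1711 against 5624 CPM and Pyy at 1383 against 3574, so that the hormone list stood at -0.23. That value turned to 0.02 when each cell weighed the same. Of these beta-like cells, 94.0% in CCR2-DTR and 43.4% in WT held an acinar UMI, against 94.1% and 43.7% of endothelial-like cells at median depths of 5605 and 5716 UMIs.

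The genotype differences of beta-like genes at 1 month and at 6 months were weakly and negatively correlated. Across 1603 genes the 1-month and 6-month genotype ratios had a Pearson correlation of -0.105 and a Spearman correlation of -0.209 (across genes, which are not independent replicates). The 10 genes highest at both ages, among those admitted by the naming rule at each age (not Sox4), were Nnat, P2ry1, Rgs2, Mdm1, Tmtc3, Gad1, the translation factor gene Eif3m, Slc38a4, the immediate early gene Egr1 and Cry2, with smaller ratios between 1.24-fold for Cry2 and Egr1 at 6 months and 1.99-fold for Nnat at 1 month. Those lowest at both ages were Lpp, Mafa, Micos10, Ndufb4, Cox7b, Ubl5, Nkx2-2, Prlr, Tomm7 and Dennd4c. For these the smaller of both ratios was at most 1.14-fold, reached by Lpp at 6 months. Ndufb4 at 6 months turned to a log2 of 0.46 in cells thinned to 2000 UMIs.

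**Figure D3:**
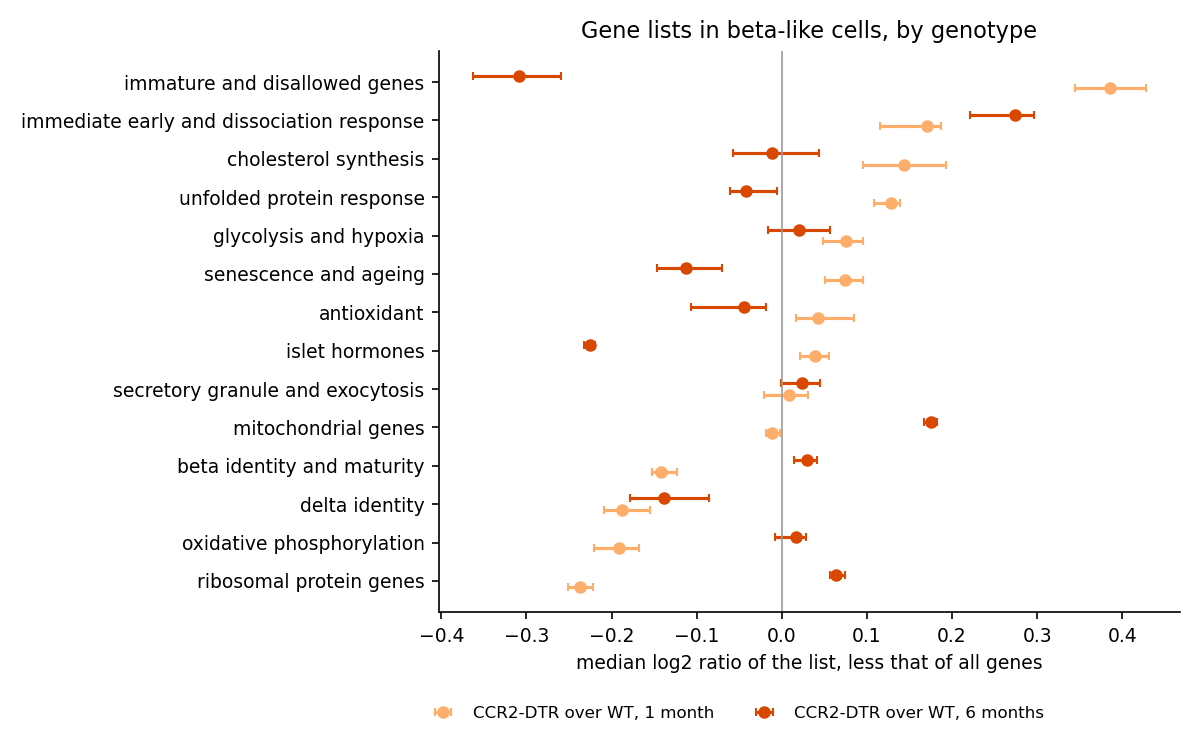
Median log2 ratio (CCR2-DTR over WT) of gene lists in beta-like cells, relative to the median of all genes, at 1 and 6 months, with 95% counting intervals from redrawn counts. Immature genes, the unfolded protein response and cholesterol synthesis lie above 0 at 1 month, and oxidative phosphorylation and ribosomal protein genes below (-0.19 and -0.24), while at 6 months immediate early genes stand highest (0.27).

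RNA of the cell cycle was far lower at 6 months than at 1 month in beta-like cells of both genotypes. In WT, 5.26% of cells (4.57 to 6.03) held UMIs of at least 3 proliferation genes at 1 month and 0.406% (0.0838 to 1.18) at 6 months, a ratio of 0.0771 (0.016 to 0.229), from 197 of 3743 and 3 of 739 thinned cells. In CCR2-DTR the shares were 6.22% (5.41 to 7.11) and 0.152% (0.0185 to 0.550), a ratio of 0.0245 (0.003 to 0.09), from 198 of 3184 and 2 of 1312 cells. The genotype ratio at 1 month was 1.18 (0.965 to 1.447), an interval that includes 1, and the 4 proliferation genes above the floor, Top2a, Stmn1, Tubb5 and Hmgb2, were all higher in CCR2-DTR (relative median 0.15). Thinning left out 41, 90, 23 and 47 cells of WT and CCR2-DTR at 1 month and then at 6 months. Without thinning the shares were 20.9%, 25.6%, 25.2% and 20.5% at median depths of 17364, 14074, 28930 and 27649 UMIs, so that the age difference in WT turned (ratio 1.21). Alpha-like cells had 1.71%, 3.48%, 0.145% and 0.917% by the thinned measure, the 0.145% being 1 cell. Their 1-month genotype ratio was 2.04 (1.382 to 3.048). Delta-like cells had 4.55%, 6.04%, 0.299% and 0.311%, with 1 cell behind each 6-month share. Without thinning the age differences in alpha-like and delta-like cells turned as well.

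**Figure D4:**
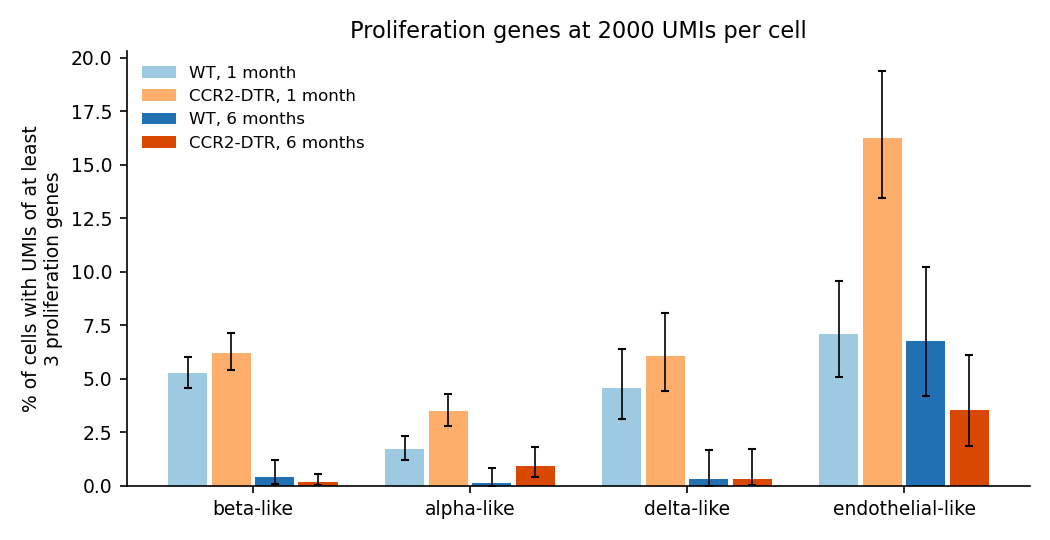
Percent of cells with a UMI of at least 3 proliferation genes after thinning to 2000 UMIs, for each class and library, with exact Clopper-Pearson 95% intervals. Beta-like, alpha-like and delta-like cells lie far lower at 6 months than at 1 month in both genotypes (beta-like WT 5.26% and 0.406%).

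With age, the genes furthest higher in WT beta-like cells were Cebpd, Cish and Nupr1, and the lowest were Stmn1 and Dapl1. Cebpd was at 73.78 against 4.285 CPM (17.2-fold, log2 4.11, 3.93 to 4.29), Cish at 58.91 against 4.914 (12-fold), and the stress gene Nupr1 at 85.77 against 9.462 (9.06-fold). Rgs2 (4.27-fold), the metallothioneins Mt2 (2.57-fold) and Mt1 (2.09-fold), Txnip, which is induced by glucose (2.54-fold), Lars2 (2.57-fold), Enpp2 (2.30-fold) and Folr1 (2.25-fold) complete the 10 highest. The lowest were Stmn1 at 5.837 against 84.92 CPM (14.5-fold lower), Dapl1 (4.90-fold), Nnat (3.53-fold), Pak3 (2.30-fold), the folding genes Fkbp11 (2.27-fold), Creld2 (2.21-fold) and Sdf2l1 (1.87-fold), Gng12 (2.15-fold), Tubb5 (2.05-fold) and Tent5a (1.79-fold). Outside the cycling cluster Tubb5 turned to a log2 of 0.11. Gng12, Fkbp11 and Sdf2l1 are among the leading genes of a beta-like cluster that held 18.5% of WT and 12.3% of CCR2-DTR beta-like cells at 1 month and 2.49% and 6.99% at 6 months. Outside it their log2 values in WT were -0.95, -1.0 and -0.71 and that of Creld2 -0.97. In CCR2-DTR the highest with age were Nupr1 at 78.92 against 4.875 CPM (16.2-fold), Mt2 (4.11-fold), Mt1 at 678.7 against 173.4 (3.91-fold), the stress factor gene Atf5 (2.36-fold) and T2 (1.78-fold). The lowest were Top2a at 0.413 against 60.75 CPM, Hmgb2 (5.19-fold lower), Car15 (4.08-fold), Creld2 (3.83-fold) and Dapl1 (3.37-fold). Across genes the age ratios of both genotypes had a Pearson correlation of 0.649 and a Spearman correlation of 0.654.

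The lists also differed with age. Oxidative phosphorylation lay below the median gene in all 39 members measured in WT (relative median -0.24, -0.26 to -0.21) and in 24 of 40 in CCR2-DTR (-0.15). The unfolded protein response was at -0.10 in WT and -0.33 in CCR2-DTR (-0.35 to -0.31, 12 of 19 below), where Sdf2l1 was at 142.8 against 433.2 CPM and Creld2 at 43.81 against 167.7, while Atf4 was at 178.9 against 112.5. With no CPM floor the CCR2-DTR value turned to 0.12, and outside the cluster with Sdf2l1 among its leading genes the WT value turned to 0.02 and the CCR2-DTR value was -0.27. Secretory granule genes were higher with age (0.11 in WT, 20 of 25 above the median gene, and 0.12 in CCR2-DTR), with Chga at 8530 against 5790 CPM in WT. Glycolysis (-0.17 and -0.34) and senescence and ageing (-0.29 and -0.44) were lower, the latter through the cyclins Ccnd1, at 92.28 against 141.2 CPM in WT, and Ccnd2, at 865.8 against 1038. Proliferation was at -2.04 and -3.75. Other lists went apart: beta identity -0.11 and 0.08, ribosomal protein genes -0.09 and 0.20, immature genes 0.17 and -0.49, antioxidant 0.13 and -0.04. In WT the hormones were at 0.15 and immediate early genes at 0.03. The WT values of antioxidant, hormones and immature genes turned sign under lower floors. The median gene itself was at 0.08 with age in WT and at -0.15 in CCR2-DTR.

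Macrophage-like cells are the class nearest to the depleted lineage. At 1 month (151 CCR2-DTR and 137 WT cells) CCR2-DTR had less RNA of interferon-induced and antigen presentation genes and more RNA of islet cells. These are differences of the whole class, which at resolution 2 divides into clusters held unequally by genotype. The one that keeps the name has H2-Ab1 and Cd74 among its leading genes, an unnamed one S100a9, Retnla and Mrc1. At 1 month the first held 90 WT and 73 CCR2-DTR cells and the second 47 and 78. At 6 months these were 62 and 90, and 32 and 69. Values below are of the whole class unless stated. All 12 measured interferon genes lay below the median gene (relative median -0.38, -0.47 to -0.23, percentile 0.225), with Irf9 at 45.9 against 83.05 CPM. All 10 MHC class II and related genes did so too (-0.27), with Cd74 at 18190 against 23720 and Cd86 at 85.94 against 147.0. Lipid-associated (-0.29), immediate early (-0.26, 20 of 21 below), ribosomal (-0.27), inflammatory cytokine (-0.19), NF-kB (-0.19) and proliferation genes (-0.29) were low. Resident macrophage genes were level by median (-0.02), with the C1q genes lower and Mrc1 at 223.6 against 130.7, Cd163 at 71.29 against 32.68 and Stab1 at 243.2 against 168.8. Monocyte-derived genes stood at 0.10. Ccr2, at 284.2 against 123.9, is on this list but does not mark monocytes cleanly between genotypes, since its RNA is higher in every main class of CCR2-DTR. In the same cells hormone genes took 13.9% of UMIs against 6.83% in WT, and beta identity (1.34, 20 of 20), secretory granule (1.10, 12 of 12) and acinar genes (2.85, 4 of 4) were all higher.

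Among the named genes at 1 month Ddit4, a stress gene, was highest at 62.5 against 10.89 CPM (log2 2.52, 1.46 to 3.79), followed by Prss53, Sytl4, Papss2, Spock2, Slc7a2, Slc7a14, Spc25, Cxxc4 and Fkbp11. Prss53 and Fkbp11 are also leading genes of beta-like clusters, and Slc7a2 of an alpha-like one. Whether islet RNA raised the other highest genes too stays open. The lowest were the chemokine gene Ccl24 at 21.48 against 84.41 CPM (log2 -1.97, -2.75 to -1.25), Zmynd15, the proton sensor gene Gpr65, Plxdc2, Olfml3, Gna15, Pmf1, Fam189a2, Tubb6 and Acsl1, all between 2.23-fold and 3.93-fold lower. With doublets kept, beta identity turned to -0.29, secretory granule genes to -0.15, acinar genes to -4.44 and Prss53, Papss2 and Fkbp11 to the other side. At resolution 2 the interferon value turned to 0.04, and Slc7a2, inflammatory cytokines and lipid-associated genes also turned, while Ccl24 had no UMI left.

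At 6 months (159 CCR2-DTR and 94 WT cells) the interferon and chemokine genes lay on the other side. Of 22 interferon genes 19 lay above the median gene (relative median 0.58, 0.39 to 0.74, percentile 100; 0.18 at a floor of 200 CPM and 0.34 with the mean of each cell's CPM), with Gbp2 at 52.33 against 10.15 CPM, Irf7 at 72.16 against 22.83 and Cxcl10 at 159.4 against 17.76 (63.2% from 1 cell). Inflammatory cytokines (1.27, 0.97 to 1.52, 6 of 8) had Ccl5 at 198.2 against 39.32 and Ccl4 at 501.1 against 232.1, while Il1b was at 199.0 against 253.7. NF-kB (0.82) and immediate early genes (0.50, 20 of 21) were higher as well. Monocyte-derived genes stood at 0.53, with S100a4 at 243.4 against 81.19 and Lyz2 at 4530 against 3033, but Chil3 at 2.379 against 69.77. Ccr2, with the same reservation, was at 310.8 against 200.4. Resident genes were lower in 10 of 12 (-0.15), with Cx3cr1 at 253.7 against 504.9. Antigen presentation (-0.10), lipid-associated (-0.05), ribosomal (0.08) and proliferation genes (0.56, 4 measured) complete the lists. Islet RNA lay the other way than at 1 month, with beta identity at -0.92 and secretory granule genes at -0.52, while acinar genes were higher (2.08). At resolution 2 the resident value turned to 0.09 and antigen presentation to 0.04, at a floor of 200 CPM the cytokine value turned to -0.20, and with no floor the proliferation value turned to -0.12.

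The 10 highest macrophage-like genes at 6 months were Lyz1, Fabp5, Ccl8, Retnla, Cfb, Ubd, the interferon-induced chemokine genes Cxcl9 and Cxcl10, Pla2g2d and Tbc1d4. A single cell held much of the RNA of several: 100% of Ubd, 99.0% of Retnla, 63.2% of Cxcl10, 56.5% of Cfb and 54.2% of Ccl8, and 39.8% of Cxcl9. Fabp5 was at 223.6 against 5.074 CPM (log2 5.46, 4.09 to 7.35) with 39.7% in 1 cell, and Lyz1 at 56.3 against 1.269 (log2 5.47, 2.95 to 10.80). Ubd and Retnla had no UMI in WT, which gives bounds of 13.5-fold and 21.3-fold by UMI counts. With nearly all their UMIs in 1 cell each, these bounds set no lower limit for the library. Among the lowest were Ccl17 at 7.929 against 121.8 CPM, 76.0% of it from 1 WT cell, the histone genes Hist1h2ae and Hist1h2ap, with 82.9% and 83.3% from 1 WT cell, Mlxipl, Ank, Cacna1d, Zfp395, Gdf3 and the interleukin receptor gene Il1r1. Mlxipl and Cacna1d are also among the leading genes of the low-UMI clusters, which score highest for beta cell markers. At resolution 2 the class kept no UMI of Ccl8, Retnla, Ubd or Pla2g2d, 2 against 0 of Cfb, 1 against 1 of Lyz1 and 5 against 4 of Tbc1d4, so their differences could not be followed there. Il1r1 turned in thinned cells (8 against 2 UMIs).

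**Figure D5:**
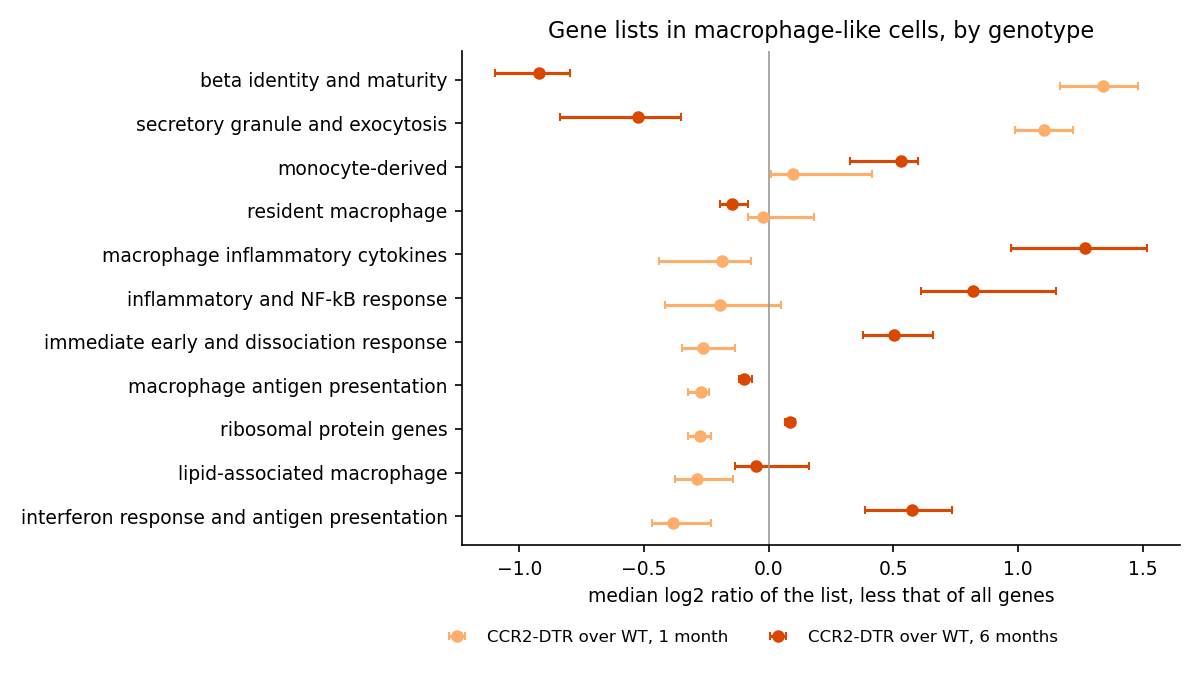
Median log2 ratio (CCR2-DTR over WT) of gene lists in macrophage-like cells, relative to the median of all genes, at 1 and 6 months, with 95% counting intervals from redrawn counts. Interferon and cytokine genes lie below 0 at 1 month (-0.38 and -0.19) and above at 6 months (0.58 and 1.27), and beta cell genes the other way.

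With age, macrophage-like cells of both genotypes had more antigen presentation RNA. In WT 9 of 10 such genes lay above the median gene (relative median 0.66, 0.52 to 0.74) and in CCR2-DTR 10 of 10 (0.91, 0.84 to 1.12). Interferon genes were higher in all 22 members in CCR2-DTR (1.11, 0.96 to 1.24) and in 10 of 14 in WT (0.32), where thinning turned the value to -0.02. Inflammatory cytokines were lower with age in WT (-1.19) and higher in CCR2-DTR (0.74). Resident genes stood at -0.02 and -0.27, the latter turned to 0.28 at resolution 2, and monocyte-derived genes at 0.11 and 0.13. The WT median gene was at -0.10. The named genes in WT were H2-M2, the chemokine receptor gene Cxcr4 and Cd300lf, higher with age, and Lyz1, Retnla and Fabp5, lower, with 67.5%, 34.4% and 50.4% of their 1-month RNA in 1 cell. In CCR2-DTR they were Cxcl9, the complement gene C3 and Pla2g2d, higher, with 39.8%, 43.8% and 34.6% from 1 cell, and Ghr, Fkbp11 and Fn1, lower. At resolution 2, Pla2g2d had 0 against 2 UMIs and Fn1 2 against 1, which leaves no sign to read.

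The lymphocytes of the CCR2-DTR 6-month library had varied profiles. Of 56 T-like cells, 35 had a UMI of Il7r, 30 of Tcf7, 30 of the chemokine gene Ccl5, 26 of Nkg7, a gene of cytotoxic cells, 17 of Cd4, 16 of Cxcr3, 10 of Ifng and 6 of Foxp3. These are 62.5%, 53.6%, 53.6%, 46.4%, 30.4%, 28.6%, 17.9% and 10.7%, against at most 0.442% of beta-like cells for any of them, at median depths of 3421 and 27649 UMIs. Of 75 B-like cells, 64 had a UMI of Ighm (85.3%, beta-like 10.6%), 46 of Ms4a1 (61.3%, beta-like 0%), 31 of Ighd, 29 of Jchain (38.7%, beta-like 2.21%), 16 of Igha (21.3%, beta-like 3.02%) and 14 of Mki67 (18.7%, beta-like 0.442%), at a median depth of 6703 UMIs. The WT 6-month library held 6 T-like and 8 B-like cells, too few for shares of genes.

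Alpha-like cells (2470 CCR2-DTR and 2374 WT at 1 month, 896 and 696 at 6 months) differed between genotypes in immediate early genes, and at 1 month had alike levels of glucagon RNA. At 6 months all 17 measured immediate early genes lay above the median gene in CCR2-DTR (relative median 0.69, 0.64 to 0.75, percentile 100), with Fos at 757.0 against 421.2 CPM, Jun at 848.1 against 509.1 and Dnajb1 at 116.5 against 52.4. At 1 month 16 of 17 lay below it (-0.16), and Hspa1b was among the lowest genes. The class joins 3 clusters in proportions that differ by library: the largest held 77.5% of WT and 83.3% of CCR2-DTR alpha-like cells at 1 month and 85.2% and 64.3% at 6 months. Within it the immediate early value was -0.09 (-0.132 to -0.069) at 1 month and 0.63 (0.572 to 0.677) at 6 months. Alpha identity genes were at -0.11 at 1 month, 14 of 17 below the median gene, and at 0.04 at 6 months. Gcg, which encodes glucagon, took 27.1% of UMIs against 26.6% at 1 month. The unfolded protein response was at 0.12 and -0.08, the latter with a sign that depended on the floor, and ribosomal protein genes at -0.31 (75 of 81 below) and 0.01. Rgs2 (2.47-fold), Sox4 (2.08-fold) and the stress gene Gadd45b (1.77-fold) were highest at 1 month, and Ghrl, which encodes ghrelin, was lowest, with 97.9% of its WT RNA in 1 cell and a log2 of 0.39 within the largest cluster, besides Tomm7. At 6 months Ier2 (2.44-fold), Dnajb1 and Junb were highest and Lars2 and Grb10 among the lowest.

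With age, immediate early genes were lower in WT alpha-like cells (-0.64, 14 of 16 below the median gene, which was at -0.11) and higher in CCR2-DTR (0.20, and 0.07, -0.001 to 0.099, within the largest cluster). Alpha identity was at -0.28 and -0.06, the CCR2-DTR value turning to 0.02 at a floor of 200 CPM and to 0.01 within the largest cluster, and ribosomal protein genes at 0.00 and 0.27. Snhg11, a neuroendocrine noncoding RNA, was higher with age in both genotypes (3.55-fold and 4.62-fold) and Olfm1 lower (2.51-fold and 2.14-fold). Upk3a in WT and Mt1 and Tmem59l in CCR2-DTR were among the other highest genes. The other lowest were Ghrl and Ier2 in WT and Hmgb2 and Enpp2 in CCR2-DTR.

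Delta-like cells repeated the immediate early pattern at 6 months, with 16 of 16 members above the median gene (0.47, 0.42 to 0.55), and at 1 month lay at -0.10. Circadian clock genes were higher in CCR2-DTR at both ages (0.31, 0.16 to 0.42, and 0.36, 0.23 to 0.48, with 4 and 5 of 6 above the median gene), with Cry2 at 135.3 against 81.4 CPM at 1 month. Proliferation genes were higher at 1 month (0.60, 7 of 8), led by Cenpf and Ube2c, as was Rgs2 at 357.7 against 165.4. The 1-month genotype ratio of delta-like cells passing the thinned proliferation measure was 1.33 (0.817 to 2.178), an interval that includes 1. Delta identity was at -0.08 and 0.04, signs that turned under other settings, and ribosomal protein genes at -0.26 and 0.04. Atp5md, Mrps21 and Hspa1b were lowest at 1 month. At 6 months Ghrl, with 58.9% in 1 cell, Dlk1 and Ppp1r17 were highest, and Lars2 and Arhgap24 among the lowest. With age, delta identity lay below the median gene in 11 of 11 members in WT (-0.32) and 8 of 11 in CCR2-DTR (-0.29), and proliferation at -2.26 and -6.32. Snhg11 and Ache were among the highest and Top2a, Stmn1 and Hmgb2 lowest with age in WT. In CCR2-DTR Ghrl, Ache and the channel gene Trpm3 were highest and Top2a, Ube2c and Mki67 lowest, and Ghrl turned at resolution 2.

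Endothelial-like cells (677 CCR2-DTR and 647 WT at 1 month, 372 and 316 at 6 months) differed at both ages, in opposite directions, in Cyp26b1, which breaks down retinoic acid. It was at 40.57 against 188.6 CPM at 1 month (log2 -2.22, -2.49 to -1.95) and at 199.9 against 7.575 at 6 months (4.72, 3.99 to 5.57), where it was the gene furthest higher. Zbtb16 (161.2 against 19.69) and Ttc39c were also highest at 6 months, and Igfbp5, which encodes a growth factor binding protein, (76.42 against 350.5) and the growth factor gene Tgfb2 (47.44 against 119.7) were among the lowest. At 1 month the highest were the cell cycle genes Prc1, Ube2c and Hist1h1b, and Hspa1b and Itgb5 were low. All 8 proliferation genes were higher at 1 month (1.73, 1.53 to 1.85), and 16.2% of CCR2-DTR and 7.10% of WT cells passed the thinned measure (ratio 2.29, 1.567 to 3.397). A small cluster of 40 CCR2-DTR and 16 WT cells led by haemoglobin genes and Mki67 held 30 of the 102 CCR2-DTR cells and 5 of the 39 WT cells that passed. Outside it the list was at 0.21 (0.044 to 0.383) and the ratio of the passing shares at 1.92 (1.258 to 2.972), from 12.2% and 6.38% of cells.

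Islet endothelium genes were below the median gene at both ages (-0.18 and -0.17), with the VEGF receptor gene Kdr at 2251 against 2754 and 2958 against 3674 CPM and Esm1 at 1501 against 1799 and 2673 against 4442. Extracellular matrix genes were at 0.15 and -0.14, and the first turned to -0.02 with automatic doublet thresholds. At 6 months interferon (0.19), immediate early (0.18) and ribosomal genes (0.08) were higher, trophic factors lower (-0.28, 5 of 6) and proliferation (0.04) and the unfolded protein response (0.06) level. At 1 month the unfolded protein response was higher (0.28, 16 of 17), ribosomal genes lower (-0.23), and interferon (-0.09), immediate early (-0.04) and trophic factor genes (0.07) near the median gene.

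With age in WT, Bmp6, Igfbp5 and Sost were highest and Cyp26b1, Zbtb16 and Sox11 lowest in endothelial-like cells. In CCR2-DTR Fmo2, Alpl and Sema5a were highest and Mki67, Top2a and Ube2c lowest. Trophic factors were higher with age (0.68 in WT, 6 of 6, with Ccn1 at 165.6 against 71.43 CPM, and 0.26 in CCR2-DTR, turned to -0.12 at a floor of 20 CPM), as were islet endothelium genes (0.19 and 0.11). Interferon genes were higher in CCR2-DTR (0.17) and level in WT (0.01, -0.127 to 0.142). Matrix genes were lower (-0.11 and -0.53), and proliferation in CCR2-DTR was at -4.11. The latter value includes the haemoglobin-led cluster, which held 40 CCR2-DTR cells at 1 month and 10 at 6 months. Outside that cluster 12.2% and 3.65% of CCR2-DTR cells passed the thinned proliferation measure.

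Mesenchymal-like cells had the fewest cells at 6 months (106 CCR2-DTR and 58 WT, against 407 and 261 at 1 month), and single cells decide several genes. Over the whole class extracellular matrix genes were higher in CCR2-DTR at both ages, with 22 of 29 above the median gene at 1 month (0.19, 0.14 to 0.25) and 24 of 28 at 6 months (0.86, 0.78 to 1.13, relative to a median gene at -0.27). The collagen genes Col1a1 (2140 against 640.0 CPM) and Col3a1 (3530 against 1240) and Mmp2 (300.4 against 18.55) stood out at 6 months. The class joins 2 clusters, and the one led by Dcn, Col1a1 and Col3a1 held 23.8% of its WT and 30.5% of its CCR2-DTR cells at 1 month and 5 of 58 (8.62%) and 38 of 106 (35.85%) at 6 months. Outside this cluster the matrix value was 0.21 (0.123 to 0.311) at 1 month and turned to -0.15 (-0.255 to -0.003) at 6 months. The 1-month value turned to -0.06 with automatic doublet thresholds. Proliferation was at 1.24 at 1 month and -3.56 at 6 months, the latter from WT genes held mostly by 1 cell, which had 92.3% of Mki67, 100% of Hist1h1b and 72.0% of Cdk1. The unfolded protein response (0.24, 17 of 18) was higher and ribosomal genes lower (-0.22) at 1 month. Outside the collagen-led cluster the 1-month values were 2.06 (1.619 to 2.48) for proliferation, 0.55 (0.455 to 0.684) for the unfolded protein response and -0.15 for ribosomal genes. Cxcl13, absent from WT and with 88.4% in 1 cell, Trf (52.8% in 1 cell) and Top2a were highest at 1 month and Ccl2, with 96.6% in 1 cell, Timp1 (61.7%) and Snai1 lowest. At 6 months Trf, with 80.0% in 1 cell, Ogn and Sned1 were highest. With age, Aspm, Hist1h1b and Prc1, with 100%, 100% and 97.1% in 1 cell, were highest in WT and Ogn, Scgn and Kcnk16 lowest. In CCR2-DTR Cxcl14 (134 UMIs against 1, log2 8.34, 5.84 to 13.66), H19 (72.4% in 1 cell) and Gbe1 (93.0% in 1 cell) were highest and Mki67, Top2a and Prc1 lowest. Hormone genes took 13%, 13.7%, 5.51% and 15.1% of the class's UMIs in WT and CCR2-DTR at 1 month and then at 6 months.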

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

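All tests of explanations in this part were chosen after the results they weigh had been seen.

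The largest group of results below is of values whose genotype difference points one way at 1 month and the other way at 6 months. With 1 library for each genotype and age, the differences between ages were not tested. Each is given as the 6-month log2 value minus the 1-month value, relative to the median gene. In alpha-like cells it was 0.15 for alpha identity, 0.85 for immediate early genes, 0.32 for ribosomal protein genes and -0.20 for the unfolded protein response. In beta-like cells it was -0.70 for immature genes, 0.17 for beta identity, -0.17 for the unfolded protein response, 0.30 for ribosomal protein genes, 0.19 for mitochondrial genes, -0.27 for islet hormones, -0.18 for senescence and ageing and -0.08 for antioxidant genes. In delta-like cells it was 0.12 for delta identity, 0.57 for immediate early genes and 0.30 for ribosomal protein genes. In endothelial-like cells it was -0.29 for extracellular matrix, 0.28 for interferon genes and 0.31 for ribosomal protein genes. In macrophage-like cells it was 0.96 for interferon genes, 1.46 for inflammatory cytokines, 0.76 for immediate early genes, 0.85 for proliferation, 0.35 for ribosomal protein genes, -2.26 for beta identity and -1.62 for secretory granule genes. In mesenchymal-like cells it was -4.80 for proliferation, where 1 WT cell holds most of the RNA. Many of these oppositions depend on the processing, since a value behind them turned sign under an alternative. In macrophage-like cells this holds for all but immediate early genes, with 1-month interferon genes at 0.04 at resolution 2. In beta-like cells it holds for all but immature and ribosomal protein genes. It also holds for delta identity, endothelial-like extracellular matrix and the alpha-like unfolded protein response. The share of beta-like cells, with genotype ratios of 0.873 at 1 month and 1.51 at 6 months, gives 1.73 as the later ratio over the earlier. This opposition depends on 2 clusters of low UMI count left unnamed, which score highest for beta cell markers: outside them the ratios were 0.9 and 1.27, and with them counted as beta-like 0.943 and 0.937, on the same side at both ages.

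Another 2 results come from barcodes that the main comparisons do not use, those above the mitochondrial limit of 15%. Their share in CCR2-DTR was 1.96 times that in WT at 1 month (18.4% and 9.37%) and again 1.96 times at 6 months (23.9% and 12.2%). Why more barcodes of the CCR2-DTR libraries passed that limit was not tested.

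RNA of digestive enzymes was in most cells of both CCR2-DTR libraries. Doublets with acinar cells are excluded as the whole source, since 94.0% of beta-like cells in CCR2-DTR at 6 months held an acinar UMI (92.6 to 95.2). Free acinar RNA in the cell suspension is a candidate source for beta-like and endothelial-like cells: at 1 month in CCR2-DTR, beta-like cells held 1.22 (1.14 to 1.30) times as many acinar UMIs per cell as endothelial-like cells, although they held 2.71 times as many UMIs in all. As the only source in macrophage-like cells it is argued against in the same library. There they held 2.37 (2.15 to 2.62) times as many acinar UMIs per cell as endothelial-like cells and 1.3 times as many UMIs in all. At 6 months in CCR2-DTR they lay closer, at 5.56 (5.2 to 5.94) against 4.72 (4.5 to 4.94) acinar UMIs per cell, which leaves that source open there. What brought the 1-month excess was not tested. Delta-like cells of CCR2-DTR at 1 month stood above most other classes too, at 2.94 acinar UMIs per cell against 1.77 in endothelial-like cells. This came through Cela1, which delta-like cells also held in WT (1.38 per cell at 1 month, endothelial-like 0.0185). Without Cela1 they stood at 1.44 against 1.6. Whether the acinar tissue itself differed by genotype, or the islets were picked less clean on those days, stays open.

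T-like and B-like cells were frequent only in CCR2-DTR at 6 months. Haemoglobin cannot decide whether blood carried along was their source, since a Ficoll gradient can part red cells from lymphocytes. Over all barcodes of the files, before any filter, 0.759% (0.571 to 0.989) held a haemoglobin UMI in that library. In WT at 6 months the share was 3.89% (3.38 to 4.46). In the same order, 6 and 16 barcodes had at least 10% of their UMIs from haemoglobin. Among barcodes under the UMI filter, 4 of 1034 and 23 of 675 held such a UMI. Red cells that never reached the listed barcodes were not analysed here. Lymph node tissue carried along cannot be told apart from lymphocytes in the islets: 58.9% of T-like cells (45.0 to 71.9) held a UMI of Ccl5 or Nkg7, genes of activated cells, but the lower bound leaves room for a minority. With 1 library, a single animal with infiltrated islets may account for these cells as well as the genotype, which stays open and untested.

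Ccr2 and Ccr3 had UMIs in cells of every main class in both CCR2-DTR libraries. Free RNA from macrophage-like cells is excluded as the whole source, although some macrophage RNA was higher there too. Of Lyz2, C1qb, C1qa, Cd74 and Tyrobp at both ages, Lyz2 at 6 months had the largest log2 ratio in the same cells, 1.54 (0.91 to 2.22), against a lower bound of 4.03 for Ccr2. At 1 month the largest was Cd74 at 0.756 (0.514 to 0.999), against a lower bound of 5.141. Whether the transgene itself brings these transcripts, with copies of this stretch of chromosome 9, stays open and untested, and how it was built is not given in the sources used here.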

How the results depend on the processing

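Of the alternatives below, 11 were chosen after seeing the data, namely those listed under data processing as added then. No paired analysis was run, since each genotype and age is 1 library of pooled islets. Turning was counted only for results whose own interval excludes no difference, and not where a count of 0 leaves a bound that points against the counts. A gene with 0 counts in both libraries gave no value. Of 2972 gene values under alternatives, 2492 stayed within their interval, 462 moved and 18 turned. For lists these were 1531, 562 and 72 of 2165, for class shares 209, 35 and 4 of 248, and for proliferation shares 110, 13 and 5 of 128. Of the results that could turn, 16 of 243 genes, 36 of 127 lists, 5 of 9 proliferation shares and 4 of 19 shares did so somewhere. Automatic thresholds left T-like and B-like cells unnamed and gave no value for them. TMM scaling shifts all genes of a library alike, so list values, being relative to the median gene, hardly test it, while 58 of 243 gene values moved and none turned under it. Counting error limits small differences in small classes: in simulated counts, 38.8% of genes with the smallest simulated change had an interval on the right side in macrophage-like cells at 6 months, and 100% in beta-like cells at 1 month. Except where the construction of an alternative is stated, the cause was not tested.

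At Leiden resolution 2, 226 macrophage-like cells become unnamed, and the named genes and lists of this class turned: at 6 months Lyz1 -0.39 (1 against 1 UMIs), Tbc1d4 -0.06 (5 against 4), antigen presentation 0.04, resident genes 0.09 and ribosomal protein genes -0.01. At 1 month Slc7a2 turned to -0.50 (7 against 11 UMIs), interferon genes to 0.04, lipid-associated genes to 0.07 and inflammatory cytokines to 0.10. With age in CCR2-DTR, Fn1 turned to 0.22 (2 against 1 UMIs), Pla2g2d to at most -0.20 (0 against 2) and resident genes to 0.28. Signs from so few UMIs are not changes of direction beyond counting error. Ccl8, Ccl17, Pla2g2d, Retnla and Ubd at 6 months and Ccl24 at 1 month had no UMI left and gave no value, nor did Retnla with age in WT, and bounds for Cfb at 6 months (2 against 0) and Lyz1 with age in WT (1 against 0) show no direction. The 1-month share ratio of macrophage-like cells moved from 1.11 to 0.819. In delta-like cells Ghrl with age in CCR2-DTR turned to -4.27 and delta identity at 6 months to -0.06.

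With doublets kept, macrophage-like cells at 1 month turned for Fkbp11 (-0.07), Papss2 (-0.29), Prss53 (-0.14), acinar genes (-4.44), beta identity (-0.29), secretory granule genes (-0.15), inflammatory cytokines (0.07) and proliferation (0.07), and islet hormones in beta-like cells to -0.23, and endothelial-like proliferation moved to 0.94. With automatic doublet thresholds, extracellular matrix at 1 month turned to -0.02 in endothelial-like and -0.06 in mesenchymal-like cells, and in beta-like cells at 1 month alpha identity turned to 0.04 and islet hormones to -0.00. Under these thresholds beta identity at 1 month moved to -0.17, the unfolded protein response to 0.10 and endothelial-like proliferation to 0.19.

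With the stricter cell filter, islet hormones in beta-like cells at 1 month turned to -0.04, the unfolded protein response moved to 0.14 and endothelial-like proliferation to 0.23. With the looser filter, islet hormones with age in WT turned to -0.07, delta identity at 6 months to -0.01, the share of delta-like cells with age in WT to 0.989, and the 1-month beta-like share ratio moved to 0.787. With enzyme and haemoglobin genes used in clustering, islet hormones at 1 month turned to -0.02, delta identity to 0.02 at 1 month and -0.04 at 6 months, and Ghrl to -4.29 with age in CCR2-DTR. The beta-like share ratios moved to 0.813 and 1.35, and the unfolded protein response with age in CCR2-DTR to -0.35. The largest dependence of a class share is on the 2 low-UMI clusters. Counted under their best class, beta-like, they turn the 6-month beta-like ratio from 1.51 to 0.937 and the ratios with age to 1.12 in WT and 1.11 in CCR2-DTR, and move the 1-month ratio to 0.943. Outside the low-UMI clusters the 6-month beta-like share ratio moved to 1.27, since these clusters hold more of the WT cells. The alpha-like ratio, whose interval includes 1, went from 1.09 to 0.916, and the endothelial-like ratio from 1.0 to 0.838.

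With totals that leave out hormone, acinar and mitochondrial genes, in beta-like cells antioxidant turned to -0.02 at 1 month and -0.14 with age in WT, islet hormones to -0.00 at 1 month and 0.02 at 6 months, and the unfolded protein response at 6 months to 0.02. In alpha-like cells the latter turned to 0.01. Oxidative phosphorylation with age in WT moved to -0.28, the unfolded protein response with age in CCR2-DTR to -0.19 and endothelial-like proliferation at 1 month to 1.08. With the mean of each cell's CPM, in beta-like cells islet hormones at 6 months turned to 0.02 and the unfolded protein response to 0.00, oxidative phosphorylation with age in WT moved to -0.28 and the unfolded protein response with age in CCR2-DTR to -0.25. Endothelial-like proliferation moved to 0.84 and macrophage-like interferon genes at 6 months to 0.34.

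In cells thinned to 2000 UMIs, Ndufb4 turned to 0.46 in beta-like cells at 6 months and Il1r1 to 1.22 in macrophage-like cells (8 against 2 UMIs), while Cdk1 (0 against 1) and Mki67 (1 against 0) in mesenchymal-like cells at 6 months show no direction. In beta-like cells glycolysis at 1 month turned to -0.02, and at 6 months senescence to 0.08, islet hormones to 0.03 and the unfolded protein response to 0.01. Delta identity turned to 0.00 at 1 month and -0.01 at 6 months, and macrophage-like interferon genes with age in WT to -0.02. Moved values were -0.12 for beta identity at 1 month, 0.17 for immediate early genes at 6 months, -0.31 for oxidative phosphorylation with age in WT, 0.10 and -0.29 for the unfolded protein response at 1 month and with age in CCR2-DTR, and 0.80 for endothelial-like proliferation.

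At a floor of 20 CPM, in beta-like cells antioxidant turned to -0.02 at 1 month and -0.14 with age in WT, islet hormones to -0.00 at 1 month and 0.02 at 6 months, and the unfolded protein response at 6 months to 0.04. It turned to 0.03 in alpha-like cells, and trophic factors in endothelial-like cells with age in CCR2-DTR to -0.12. Oxidative phosphorylation with age in WT moved to -0.28, the unfolded protein response with age in CCR2-DTR to -0.09, endothelial-like proliferation to 2.05 and macrophage-like interferon genes at 6 months to 0.75. At a floor of 200 CPM, alpha identity turned to 0.02 in alpha-like cells with age in CCR2-DTR and to 0.05 in beta-like cells at 1 month, macrophage-like inflammatory cytokines at 6 months to -0.20 and resident genes with age in CCR2-DTR to 0.05. Oxidative phosphorylation moved to -0.16, the unfolded protein response at 1 month to 0.16 and interferon genes at 6 months to 0.18. With no floor, in beta-like cells alpha identity at 1 month turned to 0.01, antioxidant to -0.06 at 1 month and -0.07 with age in WT, immature genes with age in WT to -0.04, and islet hormones to -0.15 at 1 month, 0.05 at 6 months and -0.16 with age in WT. The unfolded protein response turned to 0.10 in beta-like and 0.05 in alpha-like cells at 6 months and to 0.12 in beta-like cells with age in CCR2-DTR, and macrophage-like proliferation at 6 months to -0.12. Moved values were 0.31 for immediate early genes at 6 months, -0.31 for oxidative phosphorylation, 0.06 for the unfolded protein response at 1 month, 2.03 for endothelial-like proliferation and 0.79 for macrophage-like interferon genes.

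In beta-like cells outside the cluster of highest doublet score, antioxidant at 1 month turned to -0.03, beta identity at 6 months to -0.00, mitochondrial genes at 1 month to 0.00 and islet hormones with age in WT to -0.14, and the unfolded protein response at 1 month moved to 0.09. Without cells of another hormone, islet hormones with age in WT turned to -0.08. Outside the cycling cluster Tubb5 with age in WT turned to 0.11, and the unfolded protein response moved to 0.14 at 1 month and -0.37 with age in CCR2-DTR. Outside the folding gene cluster, antioxidant and islet hormones at 1 month each turned to -0.03, islet hormones with age in WT to -0.05 and the unfolded protein response with age in WT to 0.02, and the latter list moved to 0.18 at 1 month and -0.27 with age in CCR2-DTR. In mesenchymal-like cells outside the collagen-led cluster, extracellular matrix at 6 months turned to -0.15, at 1 month Ccl2 turned to 0.60 (8 against 3 UMIs) and Timp1 to 1.51 (10 against 2), and Gbe1 with age in CCR2-DTR to -1.27 (2 against 14). There Cxcl13 at 1 month (1 against 0) shows no direction, and Trf at 6 months and Cxcl14 and H19 with age in CCR2-DTR had no UMI and gave no value. In the largest alpha-like cluster alone, Ghrl at 1 month turned to 0.39 and alpha identity with age in CCR2-DTR to 0.01.

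Endothelial-like proliferation moved to 0.21 outside the haemoglobin-led cluster, while the ratio of proliferation shares there was 1.92, within its interval, and to 1.52 in cells under 10% hormone UMIs. That limit turned Gbe1 in mesenchymal-like cells with age in CCR2-DTR to -0.66 (5 against 16 UMIs) and left Retnla in macrophage-like cells at 6 months with 1 against 0, which shows no direction. Proliferation shares not thinned turned with age, to 1.21 in beta-like, 1.78 in alpha-like and 1.35 in delta-like cells of WT and to 1.20 in alpha-like and 1.02 in delta-like cells of CCR2-DTR, since deeper cells pass a fixed number of genes more often.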

Other observations

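No test of an explanation was run for the values in this part, all of which were noticed after the data had been seen.

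Lars2 in beta-like cells was higher in the WT library at 6 months (75.21 CPM) than in CCR2-DTR at 6 months (48.03) and WT at 1 month (29.26). A gene that stands apart in 1 library does not separate genotype from library.

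Immediate early genes were higher in CCR2-DTR at 6 months in beta-like (0.27), alpha-like (0.69), delta-like (0.47), endothelial-like (0.18) and macrophage-like cells (0.50), relative to the median gene of each class. These genes also respond to the dissociation of tissue, and no sample of undissociated islets is part of the series.

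An unnamed cluster led by Ghrl and Sst held 2.41% of cells in WT and 1.66% in CCR2-DTR at 1 month, and 1.57% and 2.10% at 6 months. It held more UMIs per cell than alpha-like or delta-like cells, a median of 15704, 12660, 32688 and 30798 in the same order.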
